A study of Mus musculus with 6 samples.

How the data were processed

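Sorted DN2 cells of fetal thymus from wild-type and E2A-deficient FVB mice were profiled on Affymetrix mouse arrays, 3 arrays per group. Per the labels, cells were sorted into lysis buffer, total RNA was purified on small-scale columns, and biotin-labelled cRNA was made by a small-sample protocol with a repeated round of in vitro transcription. The values deposited by the authors were a single intensity per probe set and array. RMA, which corrects background, normalizes by quantiles and summarises the probes of a set, is the only tool named in the submitters' processing notes, and its version is not given in the sources used here. RMA commonly returns log2 values, but the deposited intensities were linear and all positive, between 41.4 and 18824. How they were returned to the linear scale, whether they were scaled further, and whether any filter was applied is not given in the sources used here. Array medians lay between 77.4 and 79.0 and lower quartiles between 62.9 and 64.5, and no detection calls were used here. A lower bound on the intensities of that kind compresses changes of dim genes. The repeated amplification reads mostly 3' ends, so transcripts far from their 3' end are measured less well.

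The design had foreseen log2 values. Because the values were linear, log2(intensity + 1) was analysed, as the design provided for that case, with no further normalization and no filter on dim probe sets. All log2 changes are E2A deficient minus wild type on that scale. The 64 Affymetrix control probe sets were left out of the tests, which left 45037 of 45101. The annotation of the array named 1 gene for 34945 of them, several for 932 and none for 9160, and a probe set with several genes named none here. Entrez identifiers of 34741 probe sets were found in a RefSeq gene table of assembly GRCm38.p6 and 204 were not, and 0 symbols changed. That table served only for names and for which genes neighbour each other, because the sources used here name no build. Each gene took the probe set with the highest mean over the 6 arrays. Of the 18193 genes, 9010 had more than 1 probe set. Of the 630 called genes, 391 had another probe set, and 0 of these had one called in the opposite direction.

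Groups and replicate numbers were taken from the labels. The labels do not say that the replicates came from separate animals or cultures, so p-values measure only the spread between these samples. The wild-type arrays differed in Xist (3055, 4456 and 58.7) and in the Y-linked gene Eif2s3y (204, 58.0 and 343), so they did not hold the same mix of male and female cells. The number of arrays, 3 per group, limits the precision. The comparison was a linear model per gene in limma 3.58.1 (R 4.3.3) with empirical Bayes moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The same fit was run per probe set. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, with camera at an estimated correlation and with fry beside it. Camera compares a list with all other genes. Fry tests whether the genes of a list move on balance one way, and compares them with no other genes. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

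The groups, the main tests, the gene lists, the rule for naming genes and the first group of alternatives were fixed before the data were examined. The rule named Tcf3, the 15 largest rises and the 15 largest falls among called genes whose groups did not overlap, every measured member of the lists of E and Id proteins, T-lineage regulators, Notch-responsive genes and pre-TCR and rearrangement genes, and called members of the other lists, or the 3 with the smallest p. The other lists were markers of stem and progenitor, myeloid, B, NK, innate lymphoid and innate-like T, gamma-delta T, mature alpha-beta T, mast, dendritic, erythroid, thymic epithelial and mesenchymal or endothelial cells, and genes of mitosis, DNA replication, G1, apoptosis, cytokine receptors, the interferon response, the immediate-early and heat-shock response, ribosomal proteins, and sex-linked genes. List members that were not measured were left out.

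The steps were tested on simulated data made for this comparison over 18193 genes, with 200 genes changed and 20 simulations. A log2 change of 0.5 was called in 62.1% of changed genes, 1 in 91.1% and 2 in 99.5%, and 4.76% of calls were false. A list shifted by 0.5 was called in 20 of 20 simulations, and 2 of 480 tests of other lists were called. The simulated noise was independent between genes, so these list counts do not cover lists whose genes vary together. In the data the estimated correlation was 0.226 for the Notch-responsive and 0.379 for the ribosomal list. Alternatives tried were the replicate number as a block, each array left out in turn, quantile normalization, median centring, only genes brighter than the median, an intensity trend with robust variances, array weights, the mean of a gene's probe sets, probe sets with shared probes left out, other thresholds, and a test against a log2 change of 0.5. Chosen after seeing the data were the beta-actin 5'/3' ratio as a covariate, the subtraction of each array's floor before log2(intensity + 16), and the Notch-responsive and T-lineage lists without Notch1 and Notch3. RNA quality was read from the 5' and 3' control probe sets for beta-actin and Gapdh and compared by an exact permutation test.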

Results

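The data were intensities from 6 Affymetrix mouse expression arrays, 3 of wild-type and 3 of E2A-deficient cells, all on the FVB background. The cells were sorted from fetal thymus as DN2 cells. DN2 cells are thymocytes that carry neither CD4 nor CD8 and stand at the stage at which progenitors commit to the T-cell lineage. E2A is the pair of E protein transcription factors made from Tcf3, which bind DNA as dimers and are held off it by Id proteins. Each array gave 45037 probe sets beside its controls, and 34945 of these named 1 gene, which left 18193 genes. Median intensity was between 77.4 and 79.0 on the 6 arrays, and the highest probe set of each array was between 13632 and 18824. Pearson correlations across probe sets, which are not independent of each other, were 0.984 to 0.990 between arrays of 1 group and 0.975 to 0.984 between groups. The first principal component carried 49.9% of the variance and separated the 2 groups. The number of arrays limits the precision of every value below.

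The comparison asked which genes depend on E2A at this stage. Tcf3 itself was lower in E2A-deficient cells, with intensities of 236, 229 and 281 against 477, 421 and 414 in wild-type cells. In the same cells the receptors Notch1 and Notch3 and the CD3 chains Cd3e and Cd3g fell. Genes of innate lymphoid and innate-like T cells rose, among them Icos, Rora, Zbtb16 and Ahr, together with the E protein antagonist Id2 and the T-cell regulator Gata3. Of the 18193 genes, 630 differed between the groups, 437 of them higher and 193 lower in E2A-deficient cells (limma, Benjamini-Hochberg adjusted p under 0.05). Among these, 63 were higher and 39 lower by a log2 change of at least 1.

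Tcf3 changed by -0.81 on the log2 scale (SE 0.0963, n = 3 per group, limma adjusted p = 0.00532), and its other 2 probe sets were lower as well. Its signal in E2A-deficient cells, 249 ± 27.9 (SD, n = 3), stayed above the array medians. The labels do not say which part of the gene the mutation removes, so a probe set outside that part would not measure the loss. With the 5'/3' signal ratio of the beta-actin controls as a covariate the change was -0.75 and did not pass (limma adjusted p = 0.106, the highest over its alternatives, whose lowest was 9.9e-04). In the list of E proteins and Id proteins, 7 genes were measured, of which 1 rose, 1 fell and 5 did not pass, and 1 was higher and 2 lower when adjusted over the list alone. Id2 rose from 162 ± 14.4 to 442 ± 57.3 (SD, n = 3), a log2 change of 1.44 (SE 0.108, limma adjusted p = 9.71e-04). The other E protein genes Tcf12 (-0.17) and Tcf4 (0.06) and the Id genes Id1 (-0.31), Id3 (0.05) and Id4 (0.09) did not pass. The list as a group did not pass (camera adjusted p = 0.649). Its median and mean were positive, while camera, which sets the list against all other genes, pointed down.

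The 15 largest rises had log2 changes from 1.89 to 3.23. Lgals3, which encodes the lectin galectin-3, went from 69.1 ± 9.40 to 668 ± 157 (SD, n = 3; log2 change 3.23, SE 0.184). Icos, a costimulatory receptor of T cells and innate lymphoid cells, went from 96.2 ± 10.1 to 837 ± 145 (3.10, SE 0.132). The LIM-domain regulator Lmo4 went from 114 ± 5.03 to 863 ± 89.2 (2.91, SE 0.0870). The inhibitory receptor Pdcd1 (2.88) and the signalling adaptor Sh2d1a (2.46) rose with them, as did the kinase Sgk1 (2.64), the chromatin protein Hmga2 (2.63) and the sialyltransferase St6gal1 (2.51). The transcription factors Rora (2.16) and Maf (2.04) and the nuclear protein Tox2 (2.13) were also among the 15. Tox2 rested on a probe set that can hybridise to more than 1 transcript, and its other probe set, a dim one (mean log2 intensity 6.17), gave -0.028. The other probe set of St6gal1, a dim one (mean log2 intensity 6.09), gave -0.0049. Homer2 (2.99), Cd163l1 (2.01), S100a4 (1.94) and Niban1 (1.89) completed the group. In wild-type cells 13 of these 15 genes lay below the upper quartile of all probe sets, 133. Changes there are on the log2(intensity + 1) scale, with the floor of the deposited values left in, and may understate the fold. Of the 15, Cd163l1 did not pass with the beta-actin ratio as a covariate.

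The 15 largest falls had log2 changes from -2.76 to -1.42. The adhesion protein Mpzl2 fell from 576 ± 174 to 81.4 ± 5.86 (SD, n = 3), a log2 change of -2.76 (SE 0.212). The secretory-pathway gene Mzb1 changed by -2.56 and the CD3 chain Cd3g by -2.41, from 1265 ± 302 to 235 ± 38.2. Aldh1b1 (-2.23), the predicted gene Gm19696 (-2.21), Rgcc (-2.21) and 1810073O08Rik (-2.10) followed. Sh2d5 (-1.63), Rabgap1l (-1.61), Cd3e (-1.60), Rab38 (-1.55) and Uaca (-1.53) fell less, as did Notch1 (-1.46), Notch3 (-1.42) and Abtb2 (-1.42). In E2A-deficient cells 10 of the 15 lay below the same upper quartile. Rgcc and Abtb2 did not pass with the beta-actin ratio as a covariate. Limma adjusted p-values of the 30 genes lay between 2.44e-05 and 0.00752. In each gene the 3 arrays of one group lay above all 3 of the other, as the naming rule required.

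**Figure D1:**
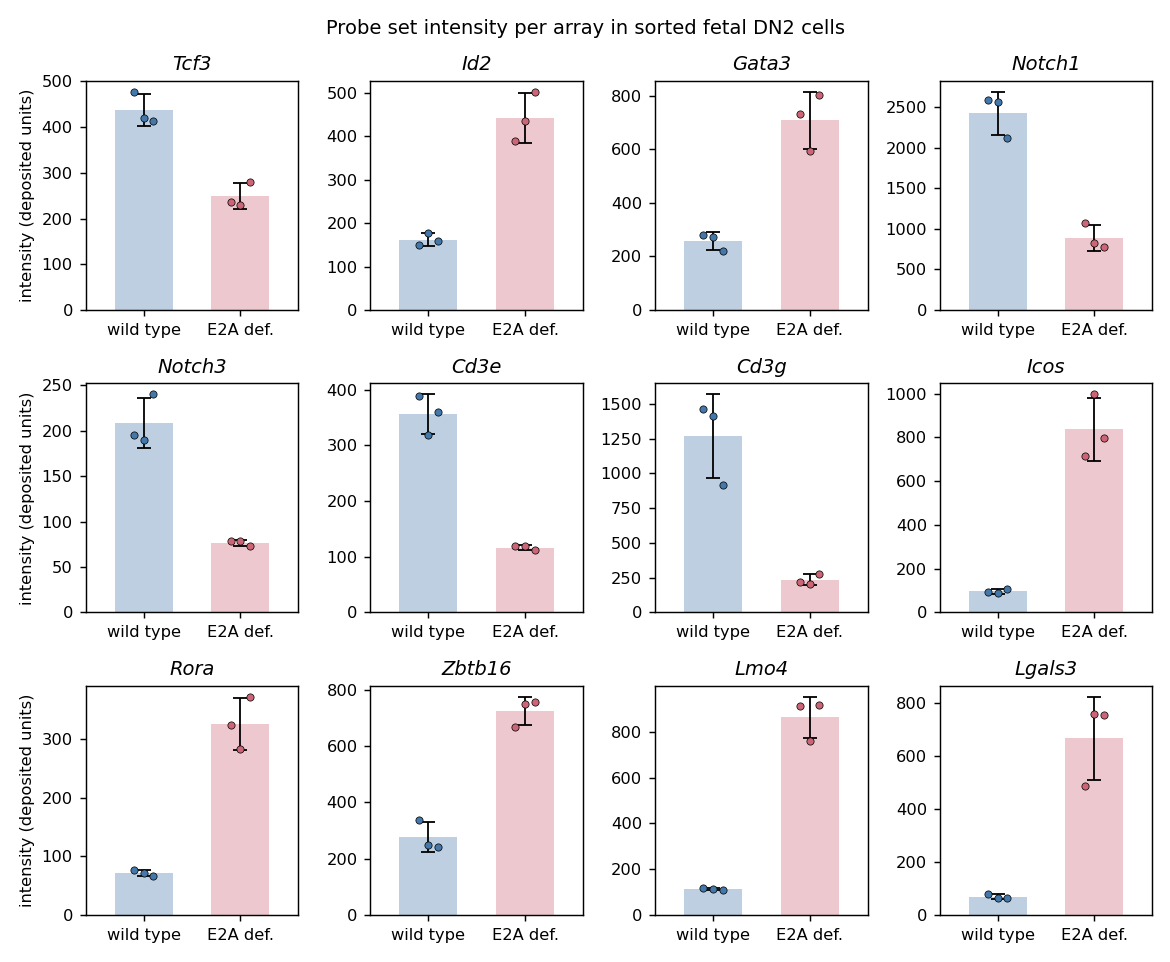
Intensity of 12 genes on each array, in deposited units, for wild-type (blue) and E2A-deficient (red) DN2 cells. Bars are means, error bars are SD over 3 arrays and points are single arrays, and in each gene the 3 points of one group lie above all 3 of the other.

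Among the genes that direct T-lineage development, 19 were measured, of which 5 rose, 6 fell and 8 did not pass. Adjusted over the list alone, 6 were higher and 8 lower. Gata3, a regulator that T cells need at every early stage, rose by 1.45 (SE 0.135), from 258 ± 33.3 to 709 ± 106 (SD, n = 3). Ikzf3 (0.99), Tox (0.93), Zfpm1 (0.83) and Lef1 (0.80) rose too. Notch1 fell from 2419 ± 265 to 885 ± 158 (SD, n = 3; log2 change -1.46, SE 0.136) and Notch3 from 208 ± 27.5 to 76.8 ± 3.24. The other probe set of Notch1 gave -0.36 and did not pass in the fit per probe set (limma adjusted p = 0.251). Notch3 was read by a probe set shared between transcripts. The probe set that is not shared, a dim one (mean log2 intensity 6.21), gave -0.19 and did not pass. The repressor Gfi1 changed by -1.11, Ets1 by -1.05, the chromatin organiser Satb1 by -0.76 and Myb by -0.40. Myb lost its call when any 1 of the 6 arrays was left out (limma adjusted p from 0.0509 to 0.154; over all its alternatives 0.00469 to 0.362). Zfpm1 lost its call without E2A-deficient replicate 1 (0.0627) or 2 (0.0646), and over all its alternatives its adjusted p was 0.00177 to 0.161. Genes that did not pass were Bcl11b (-0.42), Runx1 (-0.51), Ikzf1 (0.34), Runx3 (0.30), Patz1 (-0.16), Cbfb (-0.07), Ets2 (-0.04) and Zbtb7b (-0.03). Bcl11b, whose product closes the alternatives to the T-cell fate, passed without wild-type replicate 1 (-0.55, limma adjusted p = 0.0274; over its alternatives 0.00306 to 0.272) and with the mean of its probe sets (-0.60, 0.00306). Its 3 other probe sets were lower too, and in the fit per probe set 1 of them passed (-0.77, limma adjusted p = 0.0286) while those at -0.87 and -0.36 did not. As a group the list did not pass (camera adjusted p = 0.185). Gata3, Ikzf3, Zfpm1, Gfi1, Satb1 and Myb did not pass with the beta-actin ratio as a covariate.

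In the list of Notch-responsive genes 13 were measured, of which 3 fell and 10 did not pass, and 5 were lower when adjusted over the list alone. The 3 were the receptors Notch1 and Notch3 and the repressor Hes5 (-0.52, SE 0.0938). Hes5 lost its call without wild-type replicate 1 (0.0677) or 2 (0.0523) and without E2A-deficient replicate 1 (0.0785), 2 (0.0978) or 3 (0.109), as limma adjusted p-values, which over all its alternatives were 0.0052 to 0.257. Its probe set can also hybridise to other transcripts, and without such probe sets the change was -0.17 and did not pass. The feedback inhibitor Nrarp changed by -0.59 and the ubiquitin ligase Dtx1 by -0.33, and neither passed. Nrarp passed without E2A-deficient replicate 1 (-0.74, limma adjusted p = 0.0103; over its alternatives 0.0103 to 0.292). Other targets that did not pass were Hes1 (-0.04), the pre-TCR chain Ptcra (-0.14), Il2ra (0.13), which encodes the CD25 chain used to define the stage, and Myc (-0.32). Hey1 (0.14), Heyl (-0.12), Lfng (-0.05) and Gm266 (-0.04) did not pass either. The list was lower as a group (mean log2 change -0.37, camera adjusted p = 1.08e-05), but that call was lost with an estimated correlation (adjusted p = 0.469 with an estimated correlation, the highest over the alternatives of the whole list, whose lowest was 1.64e-07). Notch1 and Notch3 carried much of the fall, since without them, an alternative chosen after seeing the data, the mean was -0.17 (camera adjusted p = 0.00725). The mean of the whole list also went to -0.22 with the mean of probe sets, to -0.24 without probe sets shared between transcripts and to -0.57 among only genes brighter than the median, and the list passed by camera in these 3.

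Genes of the pre-TCR and of receptor gene rearrangement gave 15 measured members, of which 4 fell and 11 did not pass. Adjusted over the list alone, 1 was higher and 7 lower. The 4 were Cd3g, Cd3e, from 356 ± 35.6 to 116 ± 4.16 (SD, n = 3; log2 change -1.60, SE 0.0830), and the adaptors Lat (-1.09, SE 0.0743) and Fyb (-1.07, SE 0.110). Fyb did not pass with the beta-actin ratio as a covariate. The recombinase genes Rag1 (-0.66) and Rag2 (-0.30), the CD3 chains Cd3d (-0.41) and Cd247 (-0.10) and the kinase gene Zap70 (-0.15) did not pass. Nor did Themis (0.45), Lcp2 (0.15), Dntt (0.09), Ptcra, Xrcc6 (-0.28) and Lig4 (-0.28). The list was lower as a group (mean log2 change -0.52, camera adjusted p = 8.20e-08; adjusted p = 0.0431 with an estimated correlation).

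Markers of innate lymphoid and innate-like T cells gave 17 measured members, of which 9 rose and 8 did not pass. Adjusted over the list alone, 13 were higher and 1 lower. Icos and Rora had the smallest p-values, followed by Ahr, a ligand-activated transcription factor, which went from 239 ± 21.1 to 721 ± 79.0 (SD, n = 3; log2 change 1.59, SE 0.0983), and the chemokine receptor Cxcr6 (0.65, SE 0.0554). The list was higher as a group (mean log2 change 0.81, camera adjusted p = 1.97e-12; adjusted p = 0.0431 with an estimated correlation). Its mean was 1.40 among only genes brighter than the median and 0.60 with the mean of probe sets, and the list passed both times. In wild-type cells 3 of the 17 members lay above the upper quartile of all probe sets. Of its 9 called members, 4 did not pass with the beta-actin ratio as a covariate, namely Il4, Il18r1, Ccr6 and Cxcr5. Cxcr5 also lost its call without wild-type replicate 1 (limma adjusted p = 0.0877), 2 (0.126) or 3 (0.0925) and without E2A-deficient replicate 1 (0.124) or 3 (0.0767), against a range of 0.00324 to 0.190 over all its alternatives.

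**Figure D2:**
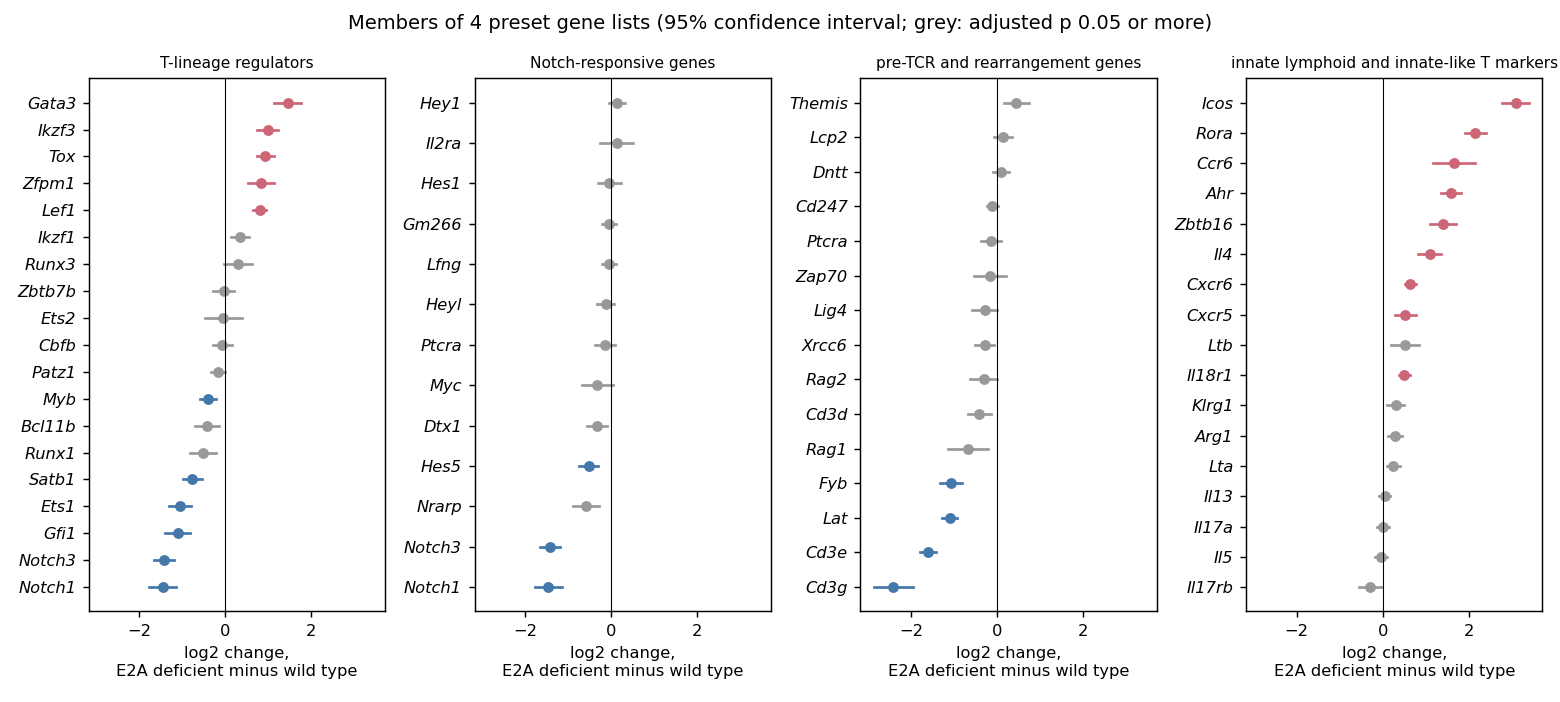
Log2 change, E2A deficient minus wild type, of each measured member of 4 gene lists, with 95% confidence intervals from 3 arrays per group. Coloured points passed the test (red higher, blue lower) and grey points did not, with 9 red points among the innate lymphoid and innate-like T markers and 4 blue points among the pre-TCR and rearrangement genes.

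Called markers of the other lymphoid fates went in both directions, except for the B-lineage list, and none of their lists passed by camera in the main test. Of the 18 gamma-delta T-cell markers fixed for the list only 8 were measured, of which 3 rose, with Maf and the receptor Cd163l1 foremost, and 1 fell. The counts were the same when adjusted over the list alone (median log2 change 0.016, camera adjusted p = 0.299). Fry, which compares a list with no other genes, called this list higher (adjusted p = 0.00264; over its alternatives 0.00264 to 0.613). Of 17 NK-cell and cytotoxic markers 4 rose and 1 fell, and 5 were higher and 2 lower when adjusted over the list alone (mean log2 change 0.20, camera adjusted p = 0.319). Among only genes brighter than the median the NK list passed (mean 0.67, camera adjusted p = 0.00416; over its alternatives 0.00416 to 0.701). The death ligand Fasl changed by -1.02, while Id2, which is shared with the Id list, and Cd7 (0.49) rose. Cd7 did not pass with the beta-actin ratio as a covariate. Of 17 markers of double-positive and mature alpha-beta T cells 2 rose and 2 fell, and 5 were higher and 2 lower when adjusted over the list alone (camera adjusted p = 0.757). They included Klf2 (0.79), Slamf1 (0.99) and Arpp21 (-1.10), of which Slamf1 did not pass with that covariate. Of 12 B-lineage markers 0 rose or fell by limma, although 3 had an unadjusted p under 0.05, and these 3 were lower when adjusted over the list alone (camera adjusted p = 0.0766). The smallest p-values belonged to Vpreb1 (-0.32) and Pou2af1 (-0.30). The B-lineage list passed downward without E2A-deficient replicate 1 (camera adjusted p = 0.0358), with an intensity trend and robust variances (0.0454) and with the mean of probe sets (0.0494), over its alternatives 0.0358 to 0.613.

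Stem and progenitor genes and myeloid genes also split. Of 19 stem and multipotent progenitor genes 3 rose and 2 fell, and 3 were higher and 5 lower when adjusted over the list alone (camera adjusted p = 0.667, pointing down against a positive median and mean). Lmo4 and the surface sialomucin Cd34 (1.07) rose and Lyl1 fell (-0.80), and Cd34 did not pass with the beta-actin ratio as a covariate. Of 19 myeloid markers 3 rose and 2 fell, with the same counts when adjusted over the list alone (camera adjusted p = 0.895), and the list passed among only genes brighter than the median (mean 0.45, camera adjusted p = 0.0493; over its alternatives 0.0493 to 0.992). The Fc receptor genes Fcgr3 (1.22) and Fcer1g (1.22) rose, both of which NK and innate lymphoid cells also use, while the granule protease Ctsg changed by -0.87. Of 13 mast-cell and basophil markers 1 rose, with the same count when adjusted over the list alone (camera adjusted p = 0.920; the median was negative and the mean positive). It was the granzyme gene Gzmb (1.19), also on the cytotoxic list, which lost its call without wild-type replicate 2 (limma adjusted p = 0.0665) or 3 (0.0568), against a range of 0.00117 to 0.166 over all its alternatives. Of 13 dendritic-cell and MHC class II markers 0 rose or fell by limma, 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.920, pointing down against a positive median and mean). Ccr2 on this list was read by its brightest probe set (log2 change 0.16, mean log2 intensity 6.66). In the fit per probe set another of Ccr2, nearly as bright (6.64), rose by 1.07 (limma adjusted p = 0.00428). A further probe set of Ccr2 rose by 0.46 (0.0436), and the last, at 0.07, did not pass. Of 9 erythroid markers 0 rose or fell by limma, 2 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.0552). The erythroid list passed upward without E2A-deficient replicate 1 (camera adjusted p = 0.00135), with an intensity trend and robust variances (0.0215), after quantile normalization (0.0275) and with the mean of probe sets (0.0323), over its alternatives 0.00135 to 0.690.

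Stromal markers gave few calls. Of 11 thymic epithelial markers 1 rose and 2 were higher when adjusted over the list alone (camera adjusted p = 0.157; fry adjusted p = 0.0126, higher; over its alternatives 0.0126 to 0.548). The called gene was the keratin gene Krt18 (0.69), which lost its call without wild-type replicate 1 (limma adjusted p = 0.0768), 2 (0.0597) or 3 (0.0887), without E2A-deficient replicate 1 (0.12) or 3 (0.133), and with the beta-actin ratio as a covariate, the highest of its alternatives at 0.371 against a lowest of 0.00497. Of 11 mesenchymal and endothelial markers 1 fell, with the same count when adjusted over the list alone (camera adjusted p = 0.372; the median was positive and the mean negative). It was the growth factor receptor gene Pdgfrb, which went from 1737 ± 82.3 to 930 ± 28.6 (SD, n = 3; log2 change -0.90, SE 0.0613).

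Genes of the cell cycle and of general cell state gave few single calls. Of 18 mitotic genes 0 rose or fell by limma, 2 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.465). Without E2A-deficient replicate 1 the mitotic list passed (camera adjusted p = 0.00135; over its alternatives 0.00135 to 0.992). Of 19 DNA replication genes 0 rose or fell by limma, 2 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.649; the median was positive and the mean negative). After quantile normalization of the deposited values the replication list passed downward (mean -0.11, camera adjusted p = 0.0036; over its alternatives 0.0036 to 0.995). Of 17 G1 regulators Rb1 alone rose (0.68) and was the 1 gene higher when adjusted over the list alone (camera adjusted p = 0.920). Rb1 did not pass with the beta-actin ratio as a covariate. Of 12 apoptosis regulators the BH3-only gene Bcl2l11 alone rose (0.54) and was the 1 gene higher when adjusted over the list alone (camera adjusted p = 0.465). Bcl2l11 lost its call without wild-type replicate 2 (limma adjusted p = 0.0525) and with the beta-actin ratio (0.152), against a lowest of 0.00852 over its alternatives.

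Of 20 cytokine and chemokine receptors 2 rose, and 5 were higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.5). They were Cxcr6 and Tnfrsf9 (0.54). Tnfrsf9 lost its call without wild-type replicate 1 (limma adjusted p = 0.0760), 2 (0.0801) or 3 (0.0910) and without E2A-deficient replicate 2 (0.101) or 3 (0.0945), and with the beta-actin ratio (0.262, the highest over its alternatives, whose lowest was 0.00702). Of 14 interferon-response genes 0 rose or fell by limma, 4 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.920). Of 17 immediate-early and heat-shock genes 0 rose or fell by limma, 1 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.895). In the list of Y-linked genes and Xist 4 were measured, of which 0 rose or fell by limma, 0 had an unadjusted p under 0.05 and 0 passed when adjusted over the list alone (camera adjusted p = 0.649). Of 49 ribosomal protein genes 0 rose or fell by limma and 0 passed when adjusted over the list alone, although 14 had an unadjusted p under 0.05, with values such as 0.52 for Rpl41. The ribosomal list was higher as a group (mean log2 change 0.14, camera adjusted p = 1.22e-04), and that call was lost with an estimated correlation (adjusted p = 0.690 with an estimated correlation, against 4.08e-09 to 0.785 over its alternatives). Its mean turned to -0.0064 after quantile normalization, and without wild-type replicate 3 it was 0.07 and did not pass (camera adjusted p = 0.0915). The list also did not pass among only genes brighter than the median (0.0539) or by fry (0.188).

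**Figure D3:**
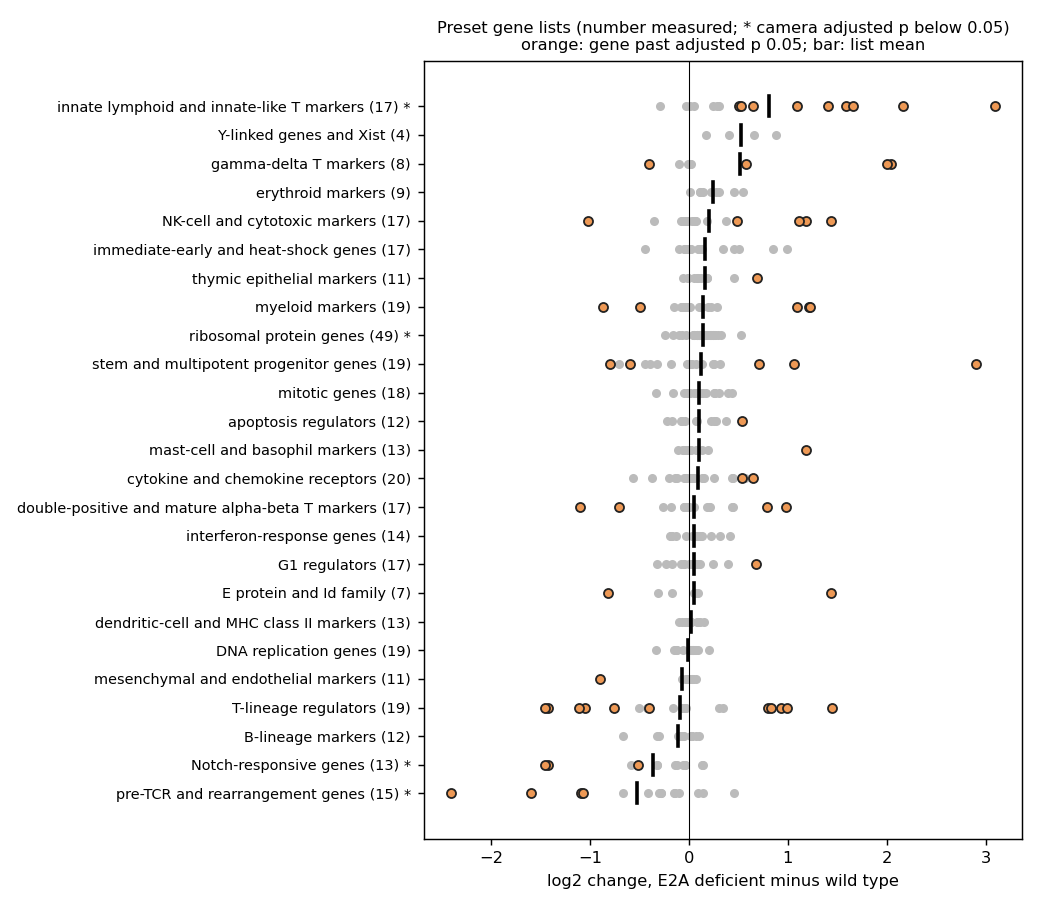
Log2 change, E2A deficient minus wild type, of every measured member of the 25 gene lists. Orange points passed the test, grey points did not, bars are list means and an asterisk marks the 4 lists with a camera adjusted p under 0.05. The ribosomal mean is above 0 here and turned to -0.0064 after quantile normalization.

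Genes were compared with limma on log2 intensities, with Benjamini-Hochberg adjustment over all genes. In all 630 genes the 3 arrays of one group lay apart from the 3 of the other, which 19.9% of all genes did and which chance gives for 10%. The separation of the 630 is no evidence beside the call, as both were read from the same values. The log2 5'/3' ratio of the beta-actin control probe sets, a sign of cDNA length and RNA quality, was -3.08 ± 0.394 in wild-type and -2.66 ± 0.0736 in E2A-deficient arrays (SD, n = 3; exact permutation p = 0.3, two-sided, the smallest possible being 0.1), and that of Gapdh was -3.64 ± 0.214 and -3.27 ± 0.227 (exact permutation p = 0.2). With the beta-actin ratio as a covariate, an alternative chosen after seeing the data, 123 genes passed, 119 of them among the 630. Quantile normalization moved the share of called genes that were higher from 69.4% to 58.3%. The count was 401 without wild-type replicate 2, 405 without 3, and 338, 381 and 320 without E2A-deficient replicate 1, 2 and 3.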

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

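Among the results in this part, the split of the arrays, the control probe set test and the Tcf3 neighbourhood were written down before their values were seen, and the tests of other cell types were chosen only after the rise of the innate lymphoid list was seen. The requirement that most genes of a set be bright enough to decide, and the count over the whole chromosome of Tcf3, were also set after those values were seen, as was the slope over all held-out arrays.

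Probe sets that name no gene lie outside the gene comparison, and 74 of them passed the limma test, 43 higher and 31 lower in E2A-deficient cells. The largest rise was that of 1439651_at, from 84.3 ± 8.69 to 614 ± 204 (SD, n = 3; log2 change 2.81), and the largest fall that of 1441858_at, from 567 ± 169 to 161 ± 24.1 (log2 change -1.78). The control probe sets lie outside it as well, and their log2 5'/3' ratio was higher in E2A-deficient than in wild-type arrays by 0.42 for beta-actin and 0.37 for Gapdh.

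For the first pattern, the 630 called genes, the tables argue against variants carried beside the mutated Tcf3 allele as its source. On the chromosome of Tcf3, besides Tcf3, 32 of 864 genes (3.70%) were called, against 597 of 17328 (3.45%) elsewhere. Of the 50 genes nearest to Tcf3 4% were called, against 3.46% of the rest (Fisher's exact p = 0.692, two-sided). Such variants stay open for single genes, such as Hmga2, Sgk1 and Myb on that chromosome and Itgb2 among the 200 nearest genes. Longer cDNA in the E2A-deficient arrays as the source was tested by wild-type replicate 2, whose control ratios lay in the E2A-deficient range. Over the genes called without it, it sat at a median of 0.132 of the way from the other wild-type arrays to the E2A-deficient mean. Replicates 1 and 3 gave 0.0847 and 0.0689, and the limit set beforehand was 0.25. That value argues against cDNA length for the called genes as a set, but it is 1 array and leaves single genes open. Each of the 6 arrays was also held out in turn, and such positions were set against those that the control ratios foretell. The slope, foretold as 1 if cDNA length were the source, was 0.0095 for beta-actin (95% interval between arrays, which are not fully independent, -0.068 to 0.087) and 0.0062 for Gapdh (-0.070 to 0.083). Unless it was itself held out, wild-type replicate 2 stayed in the wild-type group, so genes that follow the control ratios were unlikely to be called. A slope of 1 was thus hard to reach, and the slopes do not decide the question. The beta-actin covariate left 123 calls, but all 630 genes kept their sign, and the median absolute log2 change went from 0.60 to 0.57 while the median SE went from 0.0872 to 0.115 with 3 in place of 4 residual degrees of freedom. As the ratio differed between the groups, the covariate overlaps with genotype, and why single calls ended was not tested. The 10 splits of the 6 arrays are too few for a share under 0.05; the real split called 630 genes, 1 split of 10, and the highest of the others 0.

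The other pattern is the rise of the innate lymphoid and innate-like T list. For mature gamma-delta or other CD3-bearing T cells in the E2A-deficient sort, the genes every such cell uses showed no rise. Cd3e, Cd3g, Cd3d, Cd247, Lat and Zap70 had a median log2 change of -0.75 with 3 of 6 lower, Cd3g at 235 and Cd3e at 116 in E2A-deficient cells. These falls were known when the test was chosen. Wild-type DN2 cells already carried such transcripts (Cd3g at 1265), so a fall within DN2 cells could hide a minority of CD3-bearing cells. The test therefore leaves a minority of such cells open. Innate lymphoid cells stay open, because Il7r, Il2ra, Il17rb, Il5, Il13, Klrg1, Ltb, Lta and Arg1 had a median of 0.13, and 5 of these 9 lay below the upper quartile in both groups. NK cells stay open for the same reason, with a median of -0.012 over 10 genes, 8 of them below that quartile. Whether the sort for DN2 cells removed or kept either kind of cell was not tested. Apart from Il7r and Il2ra, the first set held only uncalled members of the risen list, and its median was the value of Il2ra. The NK set held only uncalled members of the NK list. As the called members of both lists were left out after their values were seen, neither median counts against these cells. A change within DN2 cells through the loss of E2A stays open too, as the biological explanation that the design names.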

How the results depend on the processing

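The beta-actin covariate, the floor subtraction and the lists without Notch1 and Notch3 were chosen after seeing the data. Where no cause is given, the cause was not tested. Counts of called genes (630; 437 higher, 193 lower) moved with the threshold by construction: 1030 (734 and 296) at adjusted p 0.1, 102 (63 and 39) with a log2 change of at least 1, and 64 (41 and 23) tested against 0.5 with treat. Called probe sets (804) became 1340 at adjusted p 0.1 and 149 with a log2 change of at least 1. With the beta-actin ratio as a covariate 123 genes passed (72 and 51), 58.5% of them higher. Leaving out 1 array, which leaves fewer arrays, gave 320 to 533 genes, 216 to 368 higher and 104 to 165 lower, 358 to 563 probe sets and 3 to 7 lists. The extra lists without E2A-deficient replicate 1 were the B-lineage, erythroid and mitotic ones.

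Deviations of same-numbered arrays correlated between -0.0417 and 0.0168, and those of differently numbered arrays between -0.0463 and 0.0268. The replicate numbers thus gave no sign of pairing, but 3 arrays per group cannot exclude it. As a block the replicate numbers gave 459 genes, 404 of them among the 630, and 471 probe sets. Other alternatives gave 592 to 753 genes. With an estimated correlation 2 lists passed in place of 4, and the Notch-responsive list (mean -0.37) did not. Among only genes brighter than the median the T-lineage list passed (mean -0.15, adjusted p = 0.0209, over its alternatives 0.0209 to 0.895). Without Notch1 and Notch3 the Notch-responsive mean was -0.17 (adjusted p = 0.00725) and the T-lineage mean 0.07 (0.895). Reversed were the ribosomal mean under quantile normalization (-0.0064) and Tox2 without shared probe sets (-0.028), which takes another, dim probe set (mean log2 intensity 6.17).

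Of 75 named called genes, 43 passed under all alternatives run for them, and 30 did not pass with the beta-actin covariate. Of 59 named genes not called, 26 of 928 alternative values passed and 24 had the other sign without passing. Of 350 alternative values of the other 22 lists, 13 passed where the main test did not and 4 no longer passed, besides the reversed ribosomal mean, which did not pass either (adjusted p = 0.785). Signal over background limits the dim genes: no floor was subtracted, and doing so gave 748 genes.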

Other observations

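The test in the last paragraph, with its requirement that most of its genes be bright, and the gene families here were chosen only after the values were seen, so the p-values of the families are not independent evidence. Ikzf1, Ikzf3 and Ctsg, like a few uncalled members, are on the fixed lists as well. Of 25 integrin genes 4 rose (limma): Itgae, the chain that binds epithelial E-cadherin, went from 60.6 ± 5.68 to 159 ± 36.8 (SD, n = 3; log2 change 1.35), and Itgb2 (1.20), Itgb3 (1.20) and Itgb7 (1.08), the partner chain of Itgae, rose with it (two-sided Fisher's exact test of called genes inside against outside the family, adjusted over 9 families, p = 0.0310). As a group the integrins did not pass (median -0.0021, camera adjusted p = 0.300). Of 15 genes of S100 calcium-binding proteins 3 rose, S100a4, S100a6 (0.95) and S100a10 (0.66), with the same adjusted p (camera adjusted p = 0.00495). Of 5 Ikaros family genes Ikzf2 (1.05, from 653 ± 76.2 to 1351 ± 108) and Ikzf3 rose, also at 0.0310 (camera adjusted p = 0.00290).

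Of 23 cathepsin genes 2 rose, Ctss (1.70) and Ctsz (0.65), and 2 fell, Ctse (-0.64) and Ctsg (-0.87), again with an adjusted Fisher's exact p of 0.0310 but without passing as a group (camera adjusted p = 0.658). Of 7 myosin I genes Myo1f (0.96) and Myo1g (0.85) rose, and of 33 semaphorin, plexin and neuropilin genes 4 rose, Sema4f (1.62), Plxnc1 (1.26), Plxnb2 (0.69) and Sema3c (0.56), both families at an adjusted Fisher's exact p of 0.0395, of which the myosins passed by camera (adjusted p = 0.0438) and the semaphorin group did not (0.597). The 8 GIMAP genes, with 1 called, did not pass by Fisher's exact test (adjusted p = 0.276) but had the smallest camera adjusted p of the 9 families, 0.00285, with a median log2 change of 0.34. The annexin genes (2 of 11 rose) and class I H2 genes (1 of 11) passed neither, with adjusted Fisher's exact p of 0.0688 and 0.321 and camera adjusted p of 0.228 and 0.303. All 23 called members of the 9 families kept their sign under quantile normalization and median centring, and all but H2-K1 passed under both. Median centring hardly moved the values (median log2 change of all genes 0.0156 against 0.0150). The families were not run with the beta-actin covariate or with arrays left out. Xist was 3055, 4456 and 58.7 and Eif2s3y 204, 58.0 and 343 in wild-type replicates 1, 2 and 3, so these arrays held different mixes of male and female cells. Xist ranged from 1247 to 2154 over the 3 E2A-deficient arrays.

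Icos, Pdcd1, Sh2d1a, Tox2 and Maf, all among the 15 largest rises, are used by follicular helper T cells. The hypothesis that a wider programme of that kind may have risen was put to genes held out from these. The median log2 change of the 13 measured was 0.03, and 0 of them were called. Cxcr5 (0.53) and Il4 (1.09), called on the innate lymphoid and innate-like T list, were not among them. As the genes were chosen after their values were seen, the median does not count against a wider programme. As a group, tested as 1 list, the 13 gave an adjusted p of 0.487 by camera in limma. In both groups 10 of the 13 lay below the upper quartile of all probe sets, so the test leaves the hypothesis open.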
